A study of Mus musculus with 6 samples.

How the data were processed

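RNA was extracted with TRIzol from mouse tail skin and made into libraries with the VAHTS Universal V5 RNA-seq kit, per the labels' protocols. There were 6 libraries, 3 from control mice and 3 labelled cKO, grouped by the genotype in the labels. The authors deposited 1 table of counts per gene and 1 table of FPKM (fragments per kilobase of gene per 1e+06 counted) for the same 18180 genes. Both tables carry gene symbols, NCBI gene numbers and pathway annotation. The deposited counts are whole numbers that were not normalized. Reads were processed with fastp, HISAT2 and HTSeq on the mm39 mouse genome, per the submitters' processing notes, which give no versions. The gene annotation, the strand setting and the treatment of reads that align to several places are not given in the sources used here. Without a stated strand setting, reads of a gene and of an antisense partner cannot be told apart, and genes with near-identical copies share reads in an unknown way. The deposited FPKM values equalled the counts divided by 1 whole-number length per gene and by the column total, within a relative tolerance of 1e-06, for all 18180 genes. The median length was 3247 bp. FPKM therefore holds the same reads as the counts and served only for alternatives. No column of values was left unmapped to a library. The reference annotation at hand was of another genome build than the deposited tables, so no coordinates are given, and it was used only to match names of the IL-36 family through gene numbers.

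Totals per library ran from 35855880 to 37043849 counts, and 3 counts, taken as the limit that a count of 0 allows, correspond to 0.0810 to 0.0837 CPM. Such limits cover counting error only. At 1000 to 3000 counts the median coefficient of variation between libraries of a group was 3.95% in both groups. The 10 genes with the most counts held 9.36% ± 0.0126 of counts in control and 10.7% ± 0.0615 in the libraries labelled cKO (SD, n = 3).

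Differences were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 15061. Library sizes were scaled by TMM, dispersions and the quasi-likelihood model were fitted with robust estimation and group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called higher or lower at an adjusted p under 0.05. Printed CPM use the TMM-scaled library sizes. Fold changes and standard errors are those of the fit, with a standard error taken as the log2 fold change divided by the square root of the F statistic. All tests were two-sided. The comparison was made over all 6 libraries, and exact permutation of 3 against 3 libraries cannot give a share under 0.1.

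Gene lists of pathways, structures and cell types were written before the data were examined. Of 885 listed names 847 were matched to the table, 844 by symbol and 3 by gene number, and 12 genes stand in 2 lists. Lists with at least 4 tested members were tested with camera of limma 3.58.1 on voom log2 CPM, with a preset correlation between genes of 0.01, and again with the correlation estimated from the data. The self-contained test fry was an alternative. Its direction says only which way a list's genes moved on balance, without comparing them with other genes.

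Genes named in the text followed a rule also written before the data were examined. It took the members of the m6A machinery list, the 12 genes with the largest rise and the 12 with the largest fall among called genes without overlap between groups, with a mean of at least 5 CPM in the higher group and no predicted, clone or antigen receptor name. It also took from each list up to 4 called members in the majority direction and up to 2 in the other, or the 2 most abundant where none was called, and a short set of keratins, cytokines and sex-linked genes always. Other genes are marked as chosen after their values were seen, and Il17f, Il22, Kdm5d, Uty and Eif2s3y were named as untested members of their lists. Pathway sets, tested after the results had been seen, come from the annotation in the deposited tables.

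Alternatives to the main analysis were DESeq2 1.42.0, limma-voom, other scaling factors, no count filter and a filter of 1 CPM in 3 libraries, limma on log2(FPKM + 1) with and without a filter of 0.5 FPKM and on log2(FPKM + 0.1) with it, the replicate number as a block, an adjusted p of 0.01, leaving out skeletal muscle and red blood cell genes, and leaving out each library in turn. Fits with an assumed BCV of 20% or 40% in edgeR's likelihood ratio test were added after the data were seen. The edgeR steps were tested on simulated counts for 14955 genes with a variance of 4 times the mean and 200 changed genes, 50 per fold size. Of genes changed 1.2-fold, 1.5-fold, 2-fold and 4-fold, 42%, 92%, 84% and 100% were recovered, with 6 false calls among 190 (3.16%), where 25 of the true calls were in a list of 30 further genes shifted by 0.5 on the log2 scale. On the same 14955 genes limma-voom made 8 false calls among 192, and DESeq2, run on all 18180 genes with its own filtering, made 21 among 207 (10.1%). On the same simulated counts camera called that list and none of 40 unshifted lists. The simulated genes were drawn independently of each other, so this does not test camera on lists of correlated genes. The simulation held no added difference between animals and few changed genes, where 61.4% of tested genes changed in the data. It therefore does not test errors between mice or the scaling when most genes change.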

Results

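RNA was sequenced from mouse tail skin in 2 groups of 3 libraries each. The control libraries came from Mettl3fl/fl mice without Cre. The other 3, labelled cKO, came from Mettl3fl/fl mice carrying K14CreERT2, a Cre recombinase that is active in basal keratinocytes after tamoxifen. Mettl3 encodes the catalytic subunit of the enzyme complex that writes N6-methyladenosine (m6A) on RNA. Per the series' design text, tissue was taken 4 weeks after 5 daily tamoxifen injections, from spontaneously inflamed areas of the tails in the Cre group and from normal tails in the controls. The comparison therefore asks which transcripts differed between inflamed tail skin of the Cre genotype and normal tail skin of the control genotype. Total gene counts were 37043849, 36115822 and 37005869 in control replicates 1 to 3 and 35855880, 36004649 and 36113956 in the libraries labelled cKO. Of 18180 genes in the count table, 15061 passed the low-count filter and were tested. Below, levels are CPM (counts per 1e+06 counts of the scaled library) given as mean ± SD over n = 3 libraries per group, always from control to the libraries labelled cKO.

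The targeted gene did not fall. Mettl3 (NCBI gene 56335) had 440, 389 and 337 counts in the control libraries and 569, 512 and 540 counts in the libraries labelled cKO. It rose from 10.7 ± 1.42 to 14.9 ± 0.832 CPM (log2 fold change 0.48, SE 0.11, adjusted p = 0.000102), which goes against the label, so every direction below is drawn for the libraries labelled cKO. The counts are for the whole gene, and exons inside and outside the floxed part were not analysed separately here. With an assumed biological coefficient of variation (BCV) of 20%, a setting chosen after the data were seen, the Mettl3 difference had an adjusted p of 0.150. Of the other 18 members of the m6A machinery list, 13 rose and none fell, which with Mettl3 makes 14 of 19 (median log2 fold change 0.23, camera adjusted p = 0.00243, adjusted p = 0.182 with an estimated correlation). Igf2bp1, an m6A reader, had the largest rise at low counts, with 11, 1 and 3 counts in control and 37, 50 and 30 in the libraries labelled cKO (log2 fold change 2.94, SE 0.61, adjusted p = 2.38e-05), and a log2 fold change of 4.21 without control replicate 1. Its relative Igf2bp2 rose 2.92-fold (from 1.22 ± 0.0858 to 3.57 ± 0.734 CPM). The reader Ythdf2 rose 2.16-fold (from 51.8 ± 2.38 to 112 ± 1.88 CPM, log2 fold change 1.11, SE 0.042, adjusted p = 2.52e-36) and the writer-complex member Rbm15 rose 2.13-fold (from 5.95 ± 0.573 to 12.7 ± 0.937 CPM). Mettl16, Virma, Ythdf1, Ythdc1, Rbm15b, Ythdf3 and Wtap rose less, with log2 fold changes from 0.71 to 0.17. The demethylases Fto and Alkbh5 had log2 fold changes of 0.26 (SE 0.063, adjusted p = 0.000255) and 0.19 (SE 0.045, adjusted p = 0.000181). Mettl14, the partner of Mettl3 in the writer complex, did not pass the test (from 20.7 ± 2.24 to 22.1 ± 2.57 CPM, adjusted p = 0.321). Neither did Cbll1, Zc3h13, Ythdc2 or Igf2bp3, with adjusted p of 0.22, 0.865, 0.715 and 0.177.

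The libraries labelled cKO held far more transcripts of wound-type keratins, small proline-rich proteins, alarm proteins and neutrophil markers than control skin. They held fewer transcripts of genes listed for hair keratins, sebaceous glands and the circadian clock. Counts from skin tissue do not show which structures of the tail skin held these transcripts. Krt6b, a keratin of injured and hyperproliferative epidermis, rose 38.7-fold (from 240.3 ± 3.86 to 9299 ± 443 CPM), and S100a9, a subunit of the alarm protein calprotectin, rose 38.2-fold (from 53.4 ± 2.17 to 2039 ± 18.5 CPM). Krt84, a type II hair keratin, fell 6.49-fold (from 15426 ± 11.5 to 2378 ± 24.1 CPM), and Scd3, a fatty acid desaturase of the sebaceous gland, fell 7.41-fold (from 70.6 ± 1.22 to 9.52 ± 1.44 CPM). Cell cycle, interferon-stimulated and dermal matrix genes were also higher, by smaller factors.

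With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 9244 genes (61.4% of those tested) changed, 4637 of them higher and 4607 lower in the libraries labelled cKO. Of these, 1623 changed at least 2-fold, 901 higher and 722 lower, and 285 rose and 160 fell at least 4-fold. The count of 1623 was 629 by limma on log2(FPKM + 1). The 2 groups did not overlap in 9781 genes (64.9%), where chance gives 10%. The first principal component held 75.7% of the variance of log2 CPM and separated the groups. The labels do not say whether the 3 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical: with assumed BCVs of 20% and 40%, both chosen after the data were seen, 3361 and 774 genes passed. Genotype and inflamed tissue went together in the design and cannot be separated here.

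Among genes that the naming rule took for their size of change, the 12 with the largest rise held 4 genes of the cornified envelope, Lce3a (38.9-fold, from 3.93 ± 0.48 to 153 ± 3.73 CPM), Lce3b, Sprr2f and Sprr2k, besides Krt6b and S100a9. The largest rise was that of Chil4, a chitinase-like protein, with 2, 2 and 4 counts in control and 229, 253 and 261 counts in the libraries labelled cKO (log2 fold change 6.48, SE 0.34, adjusted p = 7.30e-28). Pitx1, a homeobox transcription factor, followed with 4, 2 and 3 counts against 198, 250 and 199 counts (log2 fold change 6.12, SE 0.36, adjusted p = 1.42e-25). The protease inhibitor genes Csta3 and Spink7 rose 53.6-fold and 44.3-fold, the transmembrane serine protease gene Tmprss11b rose 42-fold (from 1.18 ± 0.134 to 49.7 ± 0.72 CPM), and Prl2c3 of the prolactin family rose 33.7-fold (from 0.146 ± 0.123 to 5.04 ± 0.899 CPM). The 12 genes with the largest fall held 5 keratin-associated proteins of the hair shaft, Krtap20-2, Krtap13, Krtap6-3, Krtap6-1 and Krtap6-2, which fell by 3.31 to 4.67 on the log2 scale. Scgb1a1, a secretoglobin, fell 35.1-fold (from 16.9 ± 1.46 to 0.479 ± 0.281 CPM, log2 fold change -5.13, SE 0.20, adjusted p = 9.94e-36). Il31ra, a subunit of the receptor for the itch cytokine IL-31, fell 17.6-fold (from 5.23 ± 0.763 to 0.294 ± 0.138 CPM, log2 fold change -4.14, SE 0.31, adjusted p = 4.83e-20). The metabolic enzyme genes Akr1c21, Cyp2b23 and Adh6b fell 15.9-fold, 11.9-fold and 9.96-fold. Serpinb6e fell 12.1-fold, and Paqr7, a membrane progestin receptor gene, fell 10.4-fold (from 136 ± 5.88 to 13 ± 0.525 CPM). Krtap6, Sprr2 and Lce3 genes have near-identical relatives whose reads the deposited counting could have split, so their single-gene values are uncertain.

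**Figure D1:**
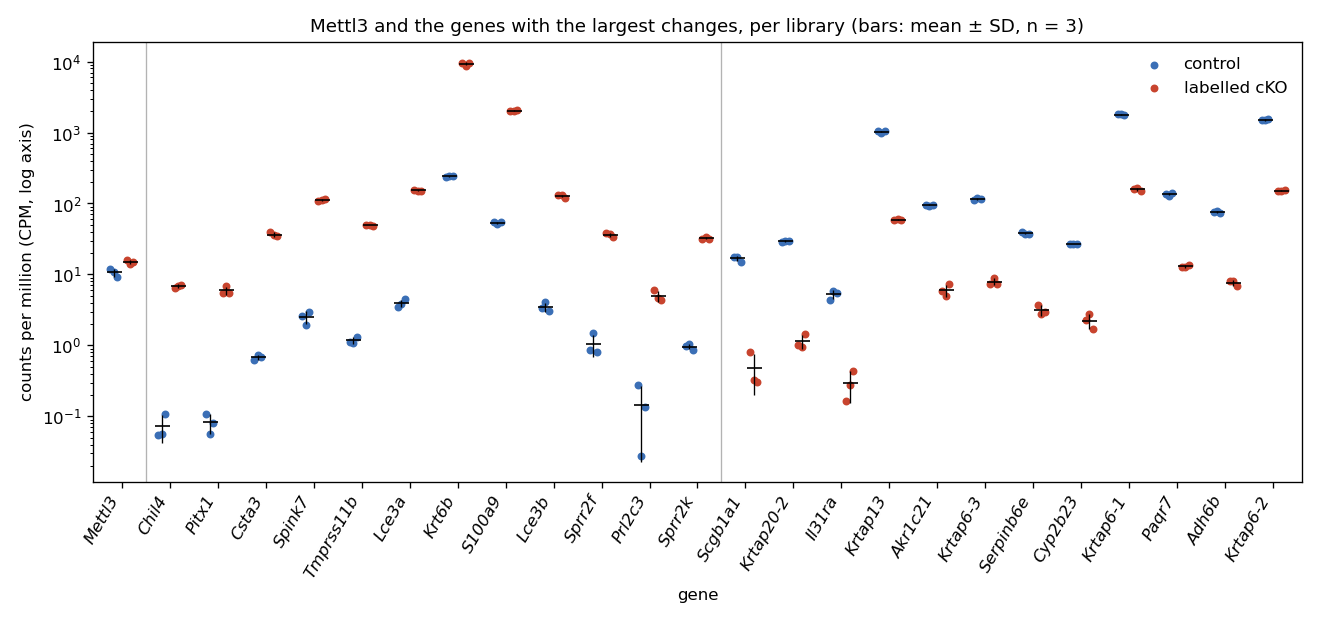
CPM per library (log axis) of Mettl3, the 12 genes with the largest rise and the 12 with the largest fall, as points for the 3 control and the 3 labelled cKO libraries with horizontal marks for the mean and bars for the SD. Groups do not overlap in any of these 25 genes, which the naming rule required of all but Mettl3. Krt6b moves from 240.3 ± 3.86 to 9299 ± 443 CPM while Krtap13 moves from 1033 ± 30.7 to 59.2 ± 0.97 CPM.

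A set of 45 gene lists was fixed before the data were examined, and 43 had at least 4 tested members. By camera with a preset correlation of 0.01, 23 lists were higher and 8 lower in the libraries labelled cKO, and 18 of these 31 also passed with an estimated correlation. For 35 lists the counts adjusted over the list alone equalled those over all genes tested, and the other 8 are given with both.

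Stress-associated keratins and small proline-rich proteins, which build the altered surface layers of wounded epidermis, made the list with the highest median. All 16 tested members rose (median log2 fold change 3.41, camera adjusted p = 5.58e-21). Krt16 rose 18.8-fold (from 445 ± 5.27 to 8384 ± 416 CPM, log2 fold change 4.24, SE 0.047, adjusted p = 1.10e-07), Krt6a rose 6.15-fold (from 1249 ± 20.1 to 7683 ± 247 CPM), and Sprr2e rose 27.3-fold (from 2.95 ± 0.785 to 80.5 ± 1.05 CPM). Krt6a and Krt6b are near-identical copies, and with Krt16 they spread widely between the libraries labelled cKO, with variances of 289, 766 and 751 times the mean. Of 16 antimicrobial and alarm protein genes, 13 rose and 1 fell (median 1.5, camera adjusted p = 5.51e-08). S100a8, the partner of S100a9, rose 33.3-fold (from 43.5 ± 1.5 to 1449.7 ± 34.7 CPM, log2 fold change 5.06, SE 0.022, adjusted p = 9.02e-97), and the beta-defensin gene Defb3 rose 29.8-fold (from 0.896 ± 0.169 to 26.8 ± 1.39 CPM). The antibacterial lectin gene Reg3g had no count in control and 76 counts over the libraries labelled cKO, at least 25.4-fold higher against a floor of 3 counts over the group, and the list's median stayed at 1.5 with this bound. Lyz1, a lysozyme gene, fell 4.29-fold (from 32.7 ± 3.19 to 7.62 ± 1.0 CPM).

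The genes of terminal differentiation and the cornified envelope split, with 20 of 32 higher and 12 lower (median 0.23, camera adjusted p = 0.00105). The suprabasal keratin gene Krt1 rose 9.44-fold (from 2170.1 ± 15.9 to 20492 ± 141 CPM, log2 fold change 3.24, SE 0.0083, adjusted p = 3.53e-114) while its partner Krt10 rose 1.4-fold (from 17342 ± 52 to 24276 ± 109.7 CPM). Repetin (Rptn) rose 11.9-fold (from 443 ± 8.51 to 5269.7 ± 24.6 CPM), Lce3f rose 19.2-fold, and filaggrin (Flg) rose 1.99-fold (from 1088 ± 6.56 to 2168 ± 21.6 CPM). Loricrin (Lor) fell 1.16-fold (from 4492 ± 17.6 to 3863 ± 24 CPM), Lce1m fell 3.9-fold (from 465 ± 5.36 to 119 ± 5.37 CPM), and Skint5 fell 9.32-fold. Krt2, a late suprabasal keratin gene chosen after its values were seen, fell 2.66-fold (from 17139.8 ± 117 to 6433 ± 72.9 CPM). Keratin genes together held 9.35% ± 0.00468 of all counts in control and 10.5% ± 0.0586 in the libraries labelled cKO.

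In the list of basal keratinocyte and hemidesmosome genes, 11 of 17 rose and 6 fell (median 0.18, camera adjusted p = 0.0329, adjusted p = 0.182 with an estimated correlation). Krt14 rose 1.85-fold (from 4157 ± 89.5 to 7687 ± 134 CPM) and Krt5 rose 1.13-fold (from 3541 ± 16.8 to 3996 ± 24.3 CPM), while Krt15, a keratin gene of quiescent basal and hair bulge cells, fell 2.07-fold (from 759.8 ± 4.46 to 368 ± 2.09 CPM). Barrier lipid genes had 13 of 20 higher and 5 lower (median 0.29, camera adjusted p = 0.00584, adjusted p = 0.0646 with an estimated correlation). The ceramide synthesis genes Degs2 and Cers3 rose 13.6-fold and 2.26-fold, and the epidermal lipoxygenase gene Aloxe3 fell 1.65-fold (from 106 ± 3.11 to 64 ± 3.77 CPM). Cell junction genes went both ways, 9 higher and 10 lower of 23 (median -0.04, mean 0.15, camera adjusted p = 0.425). The gap junction gene Gjb2 rose 2.19-fold (from 341 ± 6.74 to 747 ± 5.58 CPM) and the tight junction gene Cldn4 fell 1.46-fold (from 144 ± 5.58 to 98.5 ± 2.51 CPM).

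All 30 cell cycle genes rose (median 1.02, camera adjusted p = 3.30e-15). The proliferation marker Mki67 rose 1.87-fold (from 116 ± 3.69 to 217 ± 4.54 CPM, log2 fold change 0.91, SE 0.030, adjusted p = 1.94e-40), and the mitotic kinase gene Aurka rose 3.11-fold (from 4.97 ± 0.298 to 15.5 ± 0.917 CPM). A wider cell cycle set of 119 genes, tested after the results had been seen, had 62 higher and 26 lower (median 0.16, camera adjusted p = 0.0118, adjusted p = 0.154 with an estimated correlation). Replication-dependent histone genes had 3 of 12 higher, 2 when adjusted over the list alone, and none lower (camera adjusted p = 0.35), among them H4c9 (from 2.92 ± 0.0832 to 7.25 ± 0.365 CPM). Hypoxia and glycolysis genes had 20 of 25 higher and 1 lower, or 20 and 2 when adjusted over the list alone (median 0.81, camera adjusted p = 2.15e-11). The lactate exporter gene Slc16a3 rose 5.56-fold (from 4.39 ± 0.627 to 24.4 ± 1.53 CPM) and the glycolytic enzyme gene Eno1 rose 2.3-fold (from 374 ± 5.08 to 860.0 ± 15.1 CPM). Pdk1, a pyruvate dehydrogenase kinase gene, fell 1.46-fold. A wider glycolysis and gluconeogenesis set of 54 genes, tested after the results had been seen, had 23 higher and 17 lower (camera adjusted p = 0.439). In the list of epithelial growth signalling, 9 of 18 rose and 5 fell, or 9 and 6 when adjusted over the list alone (median 0.11, camera adjusted p = 0.283). The EGFR ligand genes Epgn, Areg and Hbegf rose 18.4-fold (from 5.32 ± 0.215 to 97.8 ± 3.02 CPM), 4.07-fold and 2.3-fold, and the receptor gene Fgfr2 fell 1.55-fold.

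In the IL-17 and IL-36 list, 16 of 20 rose and 2 fell (median 1.62, camera adjusted p = 1.33e-05). Il24 rose 82.6-fold (from 0.0456 ± 0.0566 to 4.06 ± 0.428 CPM, log2 fold change 6.37, SE 0.47, adjusted p = 4.12e-20) and Il19 rose 65.1-fold (from 0.0556 ± 0.074 to 3.8 ± 0.623 CPM, log2 fold change 6.02, SE 0.48, adjusted p = 1.28e-18). Both control means lie below the 0.0810 to 0.0837 CPM of 3 counts in a library, so the sizes of these folds are uncertain. Cxcl2, a neutrophil-attracting chemokine gene, rose 33.1-fold (from 0.657 ± 0.351 to 21.9 ± 1.3 CPM), the IL-36 alpha gene, named Il1f6 in the count table, rose 6.61-fold (from 32.2 ± 2.53 to 213 ± 1.63 CPM), and Ccl20 rose 3.12-fold. Il23a rose 6.02-fold at low levels (from 0.0924 ± 0.0903 to 0.569 ± 0.201 CPM, adjusted p = 0.00181). Il17a had 1 count over each group, Il17f 9 against 14 counts and Il22 8 against 1, too few to test, so a difference in these was not detectable at this depth. Il20 fell 3.07-fold. Of 27 IL-1, TNF and IL-6 genes, 21 rose and 3 fell, or 22 and 3 when adjusted over the list alone (median 0.86, camera adjusted p = 3.96e-05). Il1b rose 26.5-fold (from 1.74 ± 0.282 to 46.2 ± 2.97 CPM, log2 fold change 4.73, SE 0.11, adjusted p = 9.05e-51) and Osm rose 23.2-fold (from 0.0822 ± 0.0265 to 1.99 ± 0.515 CPM), while the decoy receptor gene Il1r2 fell 1.62-fold (from 56.7 ± 1.23 to 35 ± 0.379 CPM).

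All 30 tested interferon-stimulated genes rose (median 0.88, camera adjusted p = 1.33e-05), among them Cxcl9 (9.2-fold, from 0.255 ± 0.257 to 2.38 ± 0.183 CPM), Oasl2 (4.29-fold) and Ifit1 (3.96-fold). Genes of MHC class I presentation had 8 of 12 higher and 1 lower, or 8 and 2 when adjusted over the list alone (median 0.31, camera adjusted p = 0.00501, adjusted p = 0.0646 with an estimated correlation). Nlrc5, a transcriptional activator of these genes, rose 1.74-fold (from 9.64 ± 0.103 to 16.7 ± 1.41 CPM). In the type 2 inflammation list 9 of 16 rose and 6 fell (median 0.53, camera adjusted p = 0.00243, adjusted p = 0.0575 with an estimated correlation). Arg1 rose 12-fold (from 61.2 ± 2.65 to 735 ± 6.37 CPM), the epithelial alarmin genes Il33 and Tslp rose 5.49-fold and 3.46-fold, and Ccl24 and Retnla fell 2.66-fold and 2.43-fold. Arg1 and Chil3 are made by alternatively activated macrophages, and Arg1 also by keratinocytes.

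Markers of blood-derived cells were mostly higher. Of 16 neutrophil markers 15 rose and none fell (median 2.57, camera adjusted p = 1.04e-08). Trem1 rose 55.2-fold (from 0.0826 ± 0.0726 to 4.73 ± 0.875 CPM, log2 fold change 5.79, SE 0.41, adjusted p = 3.59e-21) and Stfa2 rose 22.4-fold (from 3.18 ± 0.502 to 71.5 ± 2.94 CPM). Asprv1 and Il1f9 of this list are also held by the cornified envelope and IL-36 lists. Of 21 monocyte and macrophage markers 18 rose (median 0.86, camera adjusted p = 9.08e-08), with Clec4e at 5.0-fold (from 1.14 ± 0.0827 to 5.73 ± 0.514 CPM) and Spp1 at 3.67-fold. Dendritic and Langerhans cell markers had 13 of 18 higher and none lower (median 0.67, camera adjusted p = 0.00115). The migratory dendritic cell receptor gene Ccr7 rose 11.5-fold (from 0.118 ± 0.0828 to 1.4 ± 0.726 CPM) and Itgax rose 3.23-fold, while the Langerhans cell gene Cd207, chosen after its values were seen, did not pass the test (from 4.88 ± 0.222 to 4.81 ± 0.829 CPM, adjusted p = 0.926). Of 19 T and NK cell markers 15 rose and none fell (median 1.93, camera adjusted p = 0.00309, adjusted p = 0.0575 with an estimated correlation). The T cell co-receptor genes Ctla4 and Icos rose 8.05-fold (from 0.358 ± 0.185 to 2.9 ± 0.454 CPM) and 6.15-fold (from 0.604 ± 0.41 to 3.73 ± 0.68 CPM), and Gzmb of cytotoxic cells rose 7.97-fold. Mast cell and basophil markers had 6 of 10 higher and none lower (camera adjusted p = 0.0632, and 0.0481 without replicate 3 labelled cKO), with Fcer1a at 2.98-fold (from 3.08 ± 0.258 to 9.21 ± 0.811 CPM). Of 5 B and plasma cell markers 2 rose, 1 when adjusted over the list alone (camera adjusted p = 0.235), and Sdc1, which keratinocytes also express, went from 753 ± 6.01 to 969 ± 13.8 CPM. Red blood cell markers had 6 of 8 lower and none higher (median -0.83, camera adjusted p = 0.00913, adjusted p = 0.146 with an estimated correlation), with Hba-a2 from 14.4 ± 0.297 to 7.3 ± 0.466 CPM.

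Structural cells of the dermis did not move together. Fibroblast and dermal matrix genes had 21 of 22 higher and 1 lower (median 0.48, camera adjusted p = 4.66e-15). Col3a1 rose 2.27-fold (from 2039 ± 24.1 to 4634 ± 13.3 CPM) and Col6a3 rose 2.5-fold (from 124 ± 2.45 to 309 ± 9.96 CPM), and the proteoglycan gene Dcn fell 1.27-fold (from 2495 ± 18.6 to 1967 ± 9.55 CPM). Matrix remodelling and wound repair genes had 18 of 21 higher and 2 lower (median 1.13, camera adjusted p = 5.08e-10). The collagenase gene Mmp13 rose 8.28-fold (from 1.41 ± 0.376 to 11.7 ± 0.881 CPM), the gelatinase gene Mmp9 rose 7.24-fold, tenascin C (Tnc) rose 7.2-fold (from 47 ± 1.07 to 338 ± 7.43 CPM), and Thbs1 fell 1.51-fold. Endothelial markers had 13 of 17 higher and 1 lower (median 0.47, camera adjusted p = 0.00105), led by the leukocyte adhesion genes Sele (4.18-fold, from 3.46 ± 0.451 to 14.5 ± 1.69 CPM), Selp (3.91-fold) and Vcam1 (2.86-fold). Smooth muscle and pericyte markers were mostly lower, 8 of 11 against 1 higher (median -0.51, camera adjusted p = 0.0158, adjusted p = 0.0938 with an estimated correlation), with Acta2 from 151 ± 1.83 to 98.4 ± 1.78 CPM. Schwann cell and nerve markers had 11 of 14 lower and none higher (median -0.77, camera adjusted p = 0.00044, adjusted p = 0.0575 with an estimated correlation). The myelin gene Mbp fell 2.53-fold (from 118 ± 7.38 to 46.7 ± 4.07 CPM). Adipocyte markers had 12 of 16 lower and 1 higher, or 13 and 1 when adjusted over the list alone (median -0.56, camera adjusted p = 1.77e-05). Adipoq fell 1.9-fold (from 51.6 ± 0.726 to 27.1 ± 0.826 CPM) and Cd36 fell 2.01-fold, while Thrsp, a regulator of lipogenesis, rose 1.57-fold.

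Melanocyte markers had 10 of 13 higher and 2 lower (median 0.76, camera adjusted p = 0.0375, adjusted p = 0.182 with an estimated correlation), and without control replicate 2 the list had an adjusted p of 0.0660. Trpm1 and Slc45a2 rose 2.32-fold and 2.14-fold, and the master regulator gene Mitf fell 1.57-fold (from 33.5 ± 3.36 to 21.3 ± 2.67 CPM). Skeletal muscle markers had 4 of 19 higher and 2 lower, or 3 and 2 when adjusted over the list alone (median 0.46, camera adjusted p = 0.504), with Ryr1 from 4.59 ± 0.293 to 2.17 ± 0.522 CPM and wide spread between libraries of one group. Tendon, cartilage and bone markers had 3 higher and 4 lower of 10 (median -0.25, mean 0.12, camera adjusted p = 0.516). The tendon proteoglycan gene Fmod fell 2.58-fold (from 178 ± 2.63 to 69 ± 3.64 CPM) and the cartilage matrix gene Comp rose 2.59-fold. Merkel cell and sweat gland markers had 1 higher and 2 lower of 7 (median -0.05, mean 0.17, camera adjusted p = 0.805), where the water channel gene Aqp5 rose 7.11-fold (from 6.93 ± 1.06 to 49.2 ± 1.22 CPM) and Scgb2b27 fell 1.78-fold.

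The lists of hair keratins and of sebaceous gland genes had the lowest medians of all lists tested. Of 31 hair keratin and inner root sheath genes, 30 fell and none rose (median -0.96, camera adjusted p = 3.56e-35). Krt36 fell 5.67-fold (from 13896 ± 57.8 to 2449.8 ± 4.1 CPM, log2 fold change -2.5, SE 0.0085, adjusted p = 2.63e-106) and Krtap3-1 fell 6.41-fold (from 1275 ± 18.9 to 199 ± 5.37 CPM). Together the list held 4.96% of CPM in control and 1.45% in the libraries labelled cKO, a share that weighs abundant members such as Krt84 and Krt36 most. Regulators of hair follicle stem cells and matrix had 19 of 22 lower and 1 higher (median -0.45, camera adjusted p = 0.000139, adjusted p = 0.0937 with an estimated correlation). The transcription factor genes Lhx2 and Foxn1 fell 2.07-fold (from 22.3 ± 1.5 to 10.8 ± 0.859 CPM) and 1.91-fold (from 74.8 ± 3.38 to 39.1 ± 1.09 CPM), and Foxe1 rose 1.39-fold. Sebaceous gland genes had 19 of 22 lower and 1 higher (median -0.87, camera adjusted p = 7.64e-16). Far2, which makes the fatty alcohols of wax esters, fell 3.08-fold (from 684 ± 9.54 to 222 ± 1.97 CPM), Cidea of lipid droplets fell 2.89-fold, and Acaca of fatty acid synthesis rose 1.18-fold (from 61.2 ± 3.84 to 72.2 ± 2.31 CPM). With an estimated correlation too, the lists of hair keratins, sebaceous gland and adipocyte markers were lower beside higher lists of neutrophil, monocyte and dendritic cell markers and dermal matrix in the same libraries.

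Circadian clock genes had 15 of 18 lower and 1 higher (median -0.81, camera adjusted p = 2.85e-07). Npas2 fell 3.9-fold (from 7.51 ± 0.424 to 1.92 ± 0.108 CPM, log2 fold change -1.96, SE 0.19, adjusted p = 3.66e-15), and the clock output gene Hlf and the repressor gene Cry2 fell 2.72-fold and 2.38-fold. Bhlhe40, a clock repressor gene that also responds to hypoxia, rose 1.21-fold (from 89 ± 1.5 to 107 ± 4.01 CPM). Immediate-early genes went both ways, 10 higher and 9 lower of 22 (median 0.03, camera adjusted p = 0.84), with Fosl1 rising 2.38-fold and Fosb falling 2.22-fold. Notch pathway genes had 6 higher and 5 lower of 17 (median -0.02, mean 0.09, camera adjusted p = 0.786), with the target gene Nrarp rising 1.67-fold and the ligand gene Jag2 falling 1.36-fold. Wnt pathway genes had 8 higher and 10 lower of 20 (median -0.04, camera adjusted p = 0.83), with Wnt5a rising 2.09-fold and the antagonist gene Dkk2 falling 2.09-fold. The p53 target list had 11 higher and 4 lower of 18 (median 0.25, camera adjusted p = 0.0993). Pmaip1, which promotes apoptosis, rose 3.9-fold (from 4.35 ± 0.345 to 17 ± 1.11 CPM), and Trp53inp1 fell 1.94-fold.

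Unfolded protein and integrated stress response genes had 12 of 18 higher and 4 lower (median 0.38, camera adjusted p = 0.0141, adjusted p = 0.182 with an estimated correlation). The endoplasmic reticulum folding gene Pdia4 rose 1.83-fold (from 46.6 ± 1.81 to 85.2 ± 2.49 CPM). Ppp1r15a and Chac1, both induced downstream of the transcription factor ATF4, fell 2.25-fold and 2.2-fold (from 63.4 ± 1.42 to 28.8 ± 1.15 CPM). Trib3 and Slc7a11 of the same list rose. NRF2 target genes had 10 of 16 higher and 6 lower (median 0.35, camera adjusted p = 0.0481, adjusted p = 0.143 with an estimated correlation). That list had an adjusted p of 0.0532 when scaled by library totals and of 0.0543 and 0.0540 without control replicates 1 and 3. The glutathione transferase gene Gsta4 rose 12.1-fold (from 10.7 ± 1.07 to 129 ± 3.09 CPM) and the cystine transporter gene Slc7a11 rose 2.7-fold, while Gsta3 fell 3.82-fold (from 12 ± 1.94 to 3.14 ± 0.703 CPM).

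Lists of sex-linked and of mitochondrially encoded genes could not be tested. Ddx3y had 5 counts over the control libraries and 12 over the libraries labelled cKO, Kdm5d had 1 and 1, Uty 3 and 4, and Eif2s3y 2 and 2. Xist and the mitochondrially encoded genes were not analysed here.

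**Figure D2:**
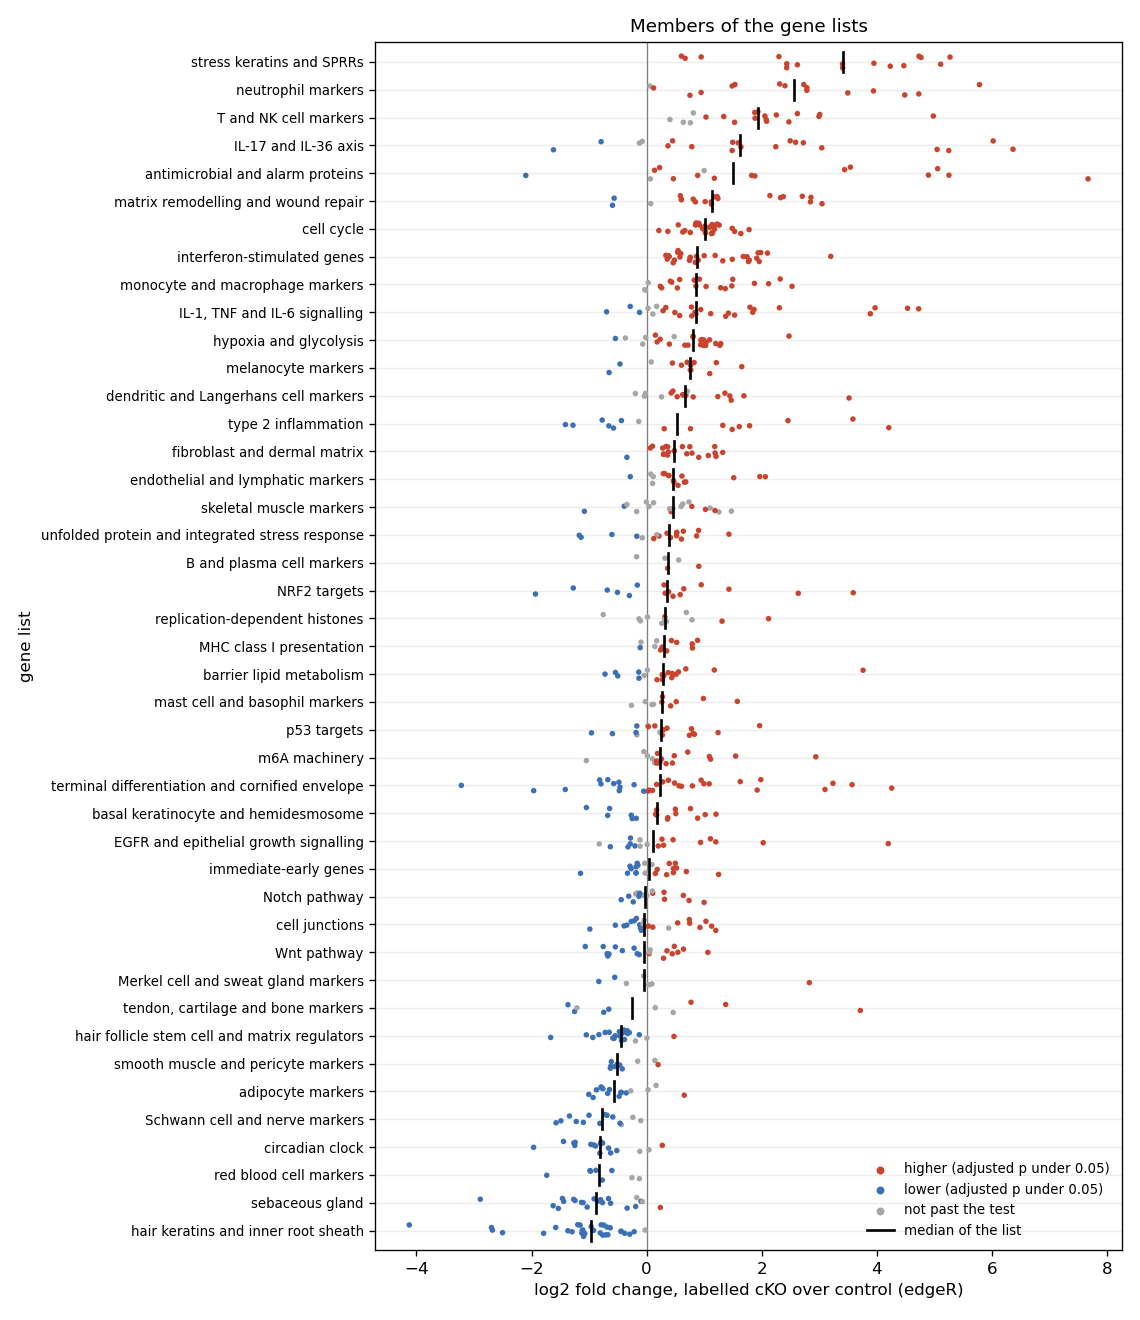
Log2 fold change (labelled cKO over control) of each tested member of the 43 lists, coloured by whether it was higher, lower or not past the test, with a black mark for the list's median. Medians run from 3.41 for stress keratins and small proline-rich proteins to -0.96 for hair keratins, and Reg3g, which had no control counts, is drawn at its fitted value.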

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

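The tests with an assumed BCV were chosen after the results had been seen, and the other alternatives beforehand. The count of 9244 changed genes ran from 7911 (adjusted p of 0.01) to 9338 (no count filter) over the alternatives chosen beforehand with all libraries, and from 8694 to 8847 without single libraries. DESeq2 gave 8951 genes and limma-voom 9329. Assumed BCVs gave fewer changed genes, and these fits also used the likelihood ratio test in place of the quasi-likelihood test. They set a wider spread than the libraries showed for genes with many counts, but not for all genes. At 20 to 50 counts the variance between libraries was 4.16 times the mean in control and 4.04 times in the libraries labelled cKO. A BCV of 20% sets less there. At 20% 3361 genes passed, 1830 higher and 1531 lower. Of the 3361, 1733 changed at least 2-fold, more than the 1623 of the main analysis, and 3182 were also called there. At 40% 774 passed, 458 higher and 316 lower, of which 774 changed at least 2-fold. The count of 1623 genes changed at least 2-fold was 629 with log2(FPKM + 1), with and without the filter, and 1123 with log2(FPKM + 0.1). The filtered fits of log2(FPKM + 1) and log2(FPKM + 0.1) differ only in the added constant, which therefore accounts for the difference between 629 and 1123. Tool, unit and filter also differ from the main analysis, and their part in the difference from 1623 was not tested. No gene called in both the main analysis and an alternative changed its sign. The Mettl3 log2 fold change of 0.48 stayed at 0.48 with assumed BCVs of 20% and 40% but lost its call (adjusted p = 0.150 and 0.948), where the range over those chosen beforehand was 2.90e-05 to 0.00567. Without single libraries it ran from 0.38 to 0.57. With an estimated correlation 18 of the 31 lists passed, and without single libraries 30 to 32 passed. Of the 258 other named genes, 47 lost their call at 20% and 144 at 40%, 3 did so with DESeq2, and 6 to 10 did so without one library. The replicate numbers did not pair the libraries: deviations of same-numbered libraries from their group means correlated across genes at -0.015, -0.015 and -0.058. With the replicate block 9250 genes changed, 30 lists passed and the melanocyte list had an adjusted p of 0.0578.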

Other observations

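All tests in this part were chosen after the results had been seen. Pathway sets from the annotation in the deposited tables were tested as further gene groups. Of 316 sets with 10 to 400 tested genes, 54 were higher and 17 lower in the libraries labelled cKO by camera with the preset correlation, and none passed with an estimated correlation, where the smallest adjusted p was 0.125 and 85 sets had an unadjusted p under 0.05. Ribosomal proteins and ribosome assembly went opposite ways. Of 132 genes of the ribosome set, 81 fell and 28 rose (median log2 fold change -0.18, camera adjusted p = 3.17e-11, adjusted p = 0.125 with an estimated correlation). Of 73 genes of ribosome biogenesis, 53 rose and 7 fell (median 0.32, camera adjusted p = 9.17e-06, adjusted p = 0.125 with an estimated correlation). The largest changes in the ribosome set were rises of mitochondrial ribosomal protein genes, such as Mrpl12 (from 49.9 ± 6.43 to 90.5 ± 3.94 CPM, 1.81-fold) and Mrpl36 (1.72-fold). The spliceosome set had 67 of 128 higher and 14 lower (camera adjusted p = 0.00374, adjusted p = 0.199 with an estimated correlation), and the aminoacyl-tRNA set had 23 of 44 higher and 3 lower (camera adjusted p = 0.0207, adjusted p = 0.145 with an estimated correlation).

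Sets of lipid and vitamin A metabolism were among the lower ones. Of 67 genes of PPAR signalling, 37 fell and 11 rose (median -0.28, camera adjusted p = 0.000741, adjusted p = 0.125 with an estimated correlation). Peroxisome genes had 42 of 77 lower and 10 higher (camera adjusted p = 0.00589, adjusted p = 0.169 with an estimated correlation). Retinol metabolism had 25 of 44 lower and 6 higher (median -0.45, camera adjusted p = 0.00354, adjusted p = 0.125 with an estimated correlation), with Aldh1a3, which makes retinoic acid, going the other way from 14.4 ± 0.274 to 85.1 ± 5.54 CPM. Mitophagy genes had 38 of 64 lower and 13 higher (camera adjusted p = 0.0176, adjusted p = 0.133 with an estimated correlation). The folate one-carbon set had 11 of 18 higher and 1 lower (camera adjusted p = 0.0413, adjusted p = 0.181 with an estimated correlation), with Mthfd2, a mitochondrial folate enzyme gene, rising 2.54-fold (from 7.9 ± 0.676 to 20.1 ± 0.70 CPM).

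Wider sets touch the subjects of fixed lists. Sets of antigen presentation (39 of 60 higher, 5 lower, camera adjusted p = 2.96e-06), IL-17 signalling (44 of 77 higher, 22 lower, camera adjusted p = 0.00142) and TNF signalling (57 of 110 higher, 24 lower, camera adjusted p = 0.0103) passed with the preset correlation. So did circadian rhythm (17 of 29 lower, 3 higher, camera adjusted p = 0.0027), and all 4 lost the call with an estimated correlation (adjusted p = 0.125 for each). Sets of p53 signalling (34 of 70 higher, 21 lower, camera adjusted p = 0.178), protein processing in the endoplasmic reticulum (65 of 160 higher, 47 lower, camera adjusted p = 0.178), chemokine signalling (70 of 166 higher, 39 lower, camera adjusted p = 0.118), Wnt signalling (34 of 149 higher, 64 lower, camera adjusted p = 0.307) and HIF-1 signalling (40 of 97 higher, 27 lower, camera adjusted p = 0.192) did not pass.

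Libraries of one group differed by a nearly constant multiple of counting noise in genes of 20 to 30000 counts, where the variance between them was 3.91 ± 0.0424 (SE) times the mean in control and 3.92 ± 0.0555 times in the libraries labelled cKO. Above that the mean ratio grew, to 7.36 and 6.19 at 30000 to 1e+05 counts and to 10.6 (19 genes) and 98.2 (21 genes) beyond, and in genes with at least 20 counts it passed 20 in 124 genes of control and 105 of the libraries labelled cKO. The ratio was 766 for Krt6b and 751 for Krt16 in the latter. Animals that differ from each other by 5% or more in most genes would make the ratio grow with the count. The fitted upper limit of such a difference, from genes under 30000 counts, was 0.722% in the group where it was higher. Of genes with at least 30000 counts, all 152 in control and all 137 in the libraries labelled cKO lay below the ratio that 5% would give, with median ratios of 4.69 and 4.08 where 5% would give 124 and 120.5. These values argue against such animals. The common BCV of 5.34% in edgeR assigns all spread beyond counting noise to biology, including the constant multiple. Repeats of 1 library would keep the ratio constant, while separate preparations from 1 pool of RNA could add a small proportional spread. At 10000 to 30000 counts the ratio was at most 1.12 times that at 20 to 100 counts. At 30000 to 1e+05 counts it was 1.8 and 1.56 times. In genes with at least 30000 counts the growth corresponds to a BCV of 0.724% in control and 1.43% in the libraries labelled cKO. Growth this small does not exclude 1 pool per group. Whether repeats of 1 source were used stays open, and the labels do not say. If they were, the p-values describe the libraries and not the spread between mice.

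Mettl3 was higher in the libraries labelled cKO, the genotype meant to lose it. An exchange of the 2 group labels would put the inflamed skin in the control group, and the stress keratin list had a median log2 fold change of 3.41 in the libraries labelled cKO, the group that the design text describes as inflamed, which argues against an exchange. A joint rise of the m6A machinery could not be decided, since the other 18 members had a camera p of 0.156 with an estimated correlation. Reads from exons outside the floxed part, or from cells without Cre such as leukocytes and fibroblasts, may also give the gene-level log2 fold change of 0.48, and without counts per exon this stays open. An effect of the inflamed state on Mettl3 in any cell type is confounded with genotype and was not tested.

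Clock genes were lower together. Collection of the groups at different times of day, if the only cause, would tend to move Arntl and Npas2 opposite to Dbp, Nr1d1 and Ciart. Arntl instead had a log2 fold change of -0.81 (SE 0.068) and Npas2 of -1.96, beside -0.80, -1.24 and -1.26. All 5 stayed lower with an assumed BCV of 20% (Arntl adjusted p = 0.00498). The mean of Arntl and Npas2 was -1.39 (SE 0.31) with that BCV even if the libraries of each group were 1 source. Peaks of these genes are not exactly opposite, so some pairs of collection times could lower both sets. The joint fall therefore does not decide whether different times were the only cause. Different times together with a common fall of clock transcripts were not tested. Dilution by cells that lack clock transcripts would lower all 18 genes by 1 common factor, but Clock (0.04) and Nfil3 (-0.12) did not pass the test, and Bhlhe40 rose in the main analysis but lost its call with a BCV of 20% (adjusted p = 0.468). The Cochran Q per degree of freedom was 85.1 with the standard errors of the fit, 4.39 with a BCV of 20% between separate libraries and 1.62 with that BCV if each group were 1 source. The last is too low to exclude a common factor, so dilution stays open. Genotype and inflammation stay open too and cannot be separated in this design, so a lower clock output in inflamed or Cre-positive skin is a hypothesis that may be followed up. Arntl, Dbp, Nr1d1, Clock and Nfil3 were chosen after their values were seen.

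Only 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many changed genes by edgeR, 9244 against at most 0 in the others. At an unadjusted p under 0.05 the real split had 9700 genes and the others 80 to 103, and 10 splits are too few for a share under 0.05. Each of the other splits mixes both groups on each side, so any difference between the groups widens the spread within its sides. Their low counts were therefore fixed in advance, and no conclusion is drawn from them. Pairs of libraries within a group had a chi-square per degree of freedom of 3.94 to 4.12 over genes and pairs between groups 363 to 371. Log2 fold change and gene length had a Spearman correlation of -0.074 across genes, which are not independent replicates, with medians of 0.04 in the shortest and -0.08 in the longest 20% of genes.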
